A study of Mus musculus with 6 samples.

How the data were processed

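RNA levels were measured on 6 Affymetrix arrays in pancreatic islets, the hormone-secreting cell clusters of the pancreas, from wild-type male mice of the outbred OF-1 stock at postnatal day 30. Their mothers had been given vehicle or bisphenol-A, a plastics monomer with estrogen-like activity, at 10 or 100 µg/kg/day between gestation days 9 and 16. The arrays form 3 groups of 2, called vehicle, BPA10 and BPA100 here, and the replicate numbers are those of the labels. Per the labels, the vehicle arrays carried RNA of 5 mice and of 1 mouse, the BPA10 arrays RNA of 1 mouse and of 2 mice, and each BPA100 array RNA of 1 mouse. RNA was isolated with a silica-column kit and amplified to biotin-labelled cRNA over 2 cycles of cDNA synthesis, per the labels' protocols.

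The deposited values are 1 intensity per probe set and array on a linear scale, computed with MAS5 per the submitters' processing notes, with a version not given in the sources used here. The scaling was read from the values: all are whole numbers from 0 upward, and with the lowest and highest 2% left out, the mean of every array lay between 149.95 and 149.96, so each array had been scaled to a target of 150. That scaling sets the arrays to one mean, so values are relative to the rest of an array's signal. The 6 arrays held 45101 probe sets, of which 64 control probe sets were left out of all tests. A platform annotation named 1 gene for 34945 probe sets, several for 932 and none for 9160, and 34741 of the first had their gene identifier in a RefSeq table of assembly GRCm38.p6, used only for names. Probe sets with several genes or none were tested but are not named. No genome build enters the array values. Detection calls were not used here.

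Values were taken as log2(signal + 1), a scale that understates changes of dim probe sets, with no further normalization. The 27022 probe sets with a mean log2 value at or above the 40th percentile of all non-control probe sets were tested, covering 13193 genes. limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) was fitted on all 6 arrays with 3 group means, so that the groups shared an estimate of the spread with 3 residual and 5.4 prior degrees of freedom. The comparisons were BPA10 against vehicle, BPA100 against vehicle, BPA100 against BPA10, the mean of both doses against vehicle, and a moderated F test over the 3 groups. Tests were 2-sided, with Benjamini-Hochberg adjustment over all probe sets of a comparison and a threshold of 0.05. Changes are given as differences of log2 group means ± the moderated standard error (SE), with 2 arrays per group. The number of arrays limits the precision: the median SE was 0.24 for 2 arrays against 2 and 0.21 for 4 against 2. Permuting group labels cannot give a 2-sided p below 0.333 for 2 arrays against 2, or below 0.0667 for 4 against 2.

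Before the data were examined, 35 gene lists were fixed, covering the cell cycle, apoptosis, islet endocrine cells, the other cell types an islet preparation can hold, stress and isolation responses, energy and lipid metabolism, insulin secretion and signalling, growth in pregnancy, estrogen and xenobiotic responses, ribosomal proteins, interferon response, chromatin regulators, genes that mature beta cells normally keep silent (disallowed genes), red blood cells and sex-linked genes. Of 998 list entries 884 were found in the annotation, 17 of them through a synonym, and 33 lists had at least 5 tested genes. Each gene was represented by its brightest tested probe set. Lists were tested with camera of limma at its preset inter-gene correlation of 0.01, which compares a list's genes with all other genes, and adjusted over the 33 lists. The alternatives were camera with the correlation estimated from these arrays, camera on ranks, and fry, which asks whether a list's genes move one way on balance without comparing them with other genes; its mixed test asks for change in either direction.

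The rule for named genes was also fixed before the data were examined. In each comparison with vehicle it takes the 8 largest rises and 8 largest falls with an adjusted p under 0.05; places left are filled by probe sets with an unadjusted p under 0.01 and all treated arrays beyond both vehicle arrays, and predicted genes are skipped. It adds the 4 members with the smallest p in the direction of each list that passed, and 32 islet, cell cycle, apoptosis, estrogen receptor and acinar genes reported in every comparison. Of these 32, 23 were tested. Cdkn2a, Esr1 and Esr2 lay below the brightness filter, and 6 are not analysed here. For BPA100 against BPA10 the rule takes the 3 largest of each direction. As no probe set passed, every gene named under the first part filled a place left and did not pass.

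The other settings tried were quantile normalization, centring each array on its median, a pseudocount of 16, no filter, a filter at the 60th percentile, no intensity trend, a robust spread, array weights, only the groups compared, the mean of a gene's probe sets, only the arrays made from 1 mouse, the replicate number as a block, and each array left out in turn. The mean of the acinar-cell list as a covariate was added after the data were seen. Where a setting left a group with 1 array, that array was assumed to vary like the groups that kept both. With only arrays of 1 mouse, vehicle and BPA10 each kept 1 array, so the spread came from the BPA100 arrays alone.

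The fit was tested on simulated data with the real means and the fitted prior of the spread. In 10 runs over 27022 probe sets with 50 changed per fold, the BPA10 against vehicle comparison called 15.8% of 2-fold, 46.6% of 3-fold and 61.2% of 4-fold changes, and the mean of both doses 28%, 62% and 70.8%. For BPA100 against vehicle the shares were 15.6%, 50.2% and 64.4%, and for BPA100 against BPA10 15.6%, 50.4% and 63.2%. At 1.5-fold they were between 0.4% and 3%. For the mean of both doses, a list of 49 independent genes among 13193, all shifted by 0.5 on the log2 scale, was called in 10 of 10 runs with the preset correlation, in 7 with the estimated correlation and in 9 with fry. At a shift of 0.75 each called it in 10 of 10 runs, and at 0.25 in 10, 0 and 4. These simulated genes were independent, unlike real ones, so the shares do not apply to correlated lists.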

Results

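Gene expression was compared in islets of 30-day-old male mice whose mothers had received vehicle, 10 or 100 µg/kg/day of bisphenol-A in mid to late gestation (groups vehicle, BPA10 and BPA100, with 2 arrays each). The question of the series is how such exposure in the womb affects the growth of the insulin-producing beta cells in early life. Median signals lay between 33 and 40 per array and the highest between 11218 and 15158. Over the 27022 probe sets tested, the correlation between arrays of the same group was 0.968 in each of the 3 groups, within the range of 0.945 to 0.975 over all pairs of arrays. The labels do not give the litter of origin, so limma p-values measure only the spread between arrays. Camera p-values at the preset correlation come mainly from the spread over genes, so they do not measure the spread between arrays or mice. Between 1.3% and 2.0% of values were identical in a pair of arrays.

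In islets of BPA10 offspring, genes of mitosis and cytokinesis were higher than in vehicle offspring. The mean change over the 49 measured genes was 0.88 on the log2 scale, or 1.85-fold, with 47 genes higher and 2 lower. The largest differences were in Hmmr, a spindle protein and hyaluronan receptor, Nek2, a centrosome kinase, Cdc20, the activator of the anaphase-promoting complex, and Ube2c, the ubiquitin-conjugating enzyme of that complex. Markers of the enzyme-secreting acinar cells of the exocrine pancreas were higher on the same arrays, by a mean of 1.22 with 30 of 30 genes higher. The mean of the replication genes of S phase differed by 0.12 and that of the beta-cell identity genes by 0.06, and neither list passed its test.

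The mitosis list rose in BPA10 islets (camera adjusted p = 9.3e-35; adjusted p = 0.467 with an estimated correlation). Relative to the vehicle mean it stood at 0.87 and 0.90 on the BPA10 arrays, against 0.12 and -0.12 on the vehicle arrays. Of its 49 genes, 35 were higher at an unadjusted p under 0.05, 0 passed over all probe sets with limma, and 33 passed when adjusted over the list alone. Hmmr had a signal of 49 and 45 on the vehicle arrays and 171 and 181 on the BPA10 arrays, a difference of 1.88 ± 0.19 (SE; adjusted p = 0.182), and its 3 other probe sets differed by 0.96 to 1.61. Cdc20 measured 136 and 97 against 332 and 377 (1.61 ± 0.20, adjusted p = 0.194) and Ube2c 76 and 59 against 200 and 213 (1.61 ± 0.20, adjusted p = 0.194). Nek2 differed by 1.84 ± 0.27, but its 2 other probe sets gave -0.40 and 0.87. Among the cell division genes chosen beforehand, Mki67, a marker of cycling cells, measured 128 and 136 against 235 and 279 (0.95 ± 0.17, adjusted p = 0.315). The mitotic kinase Cdk1 differed by 0.88, Top2a by 0.55 and Ccna2 by 0.37. The G1 genes Ccnd2 and Cdk4 differed by 0.15 (-0.08 after quantile normalization) and -0.26, and the cell cycle inhibitors Cdkn1a and Cdkn1b by 0.09 and 0.18, but the other probe sets of these inhibitors gave -1.04 and -0.11. Other probe sets of Ccnd2 lay between -0.18 and 0.22 and of Cdk4 between -0.16 and 0.10. None of these passed.

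**Figure D1:**
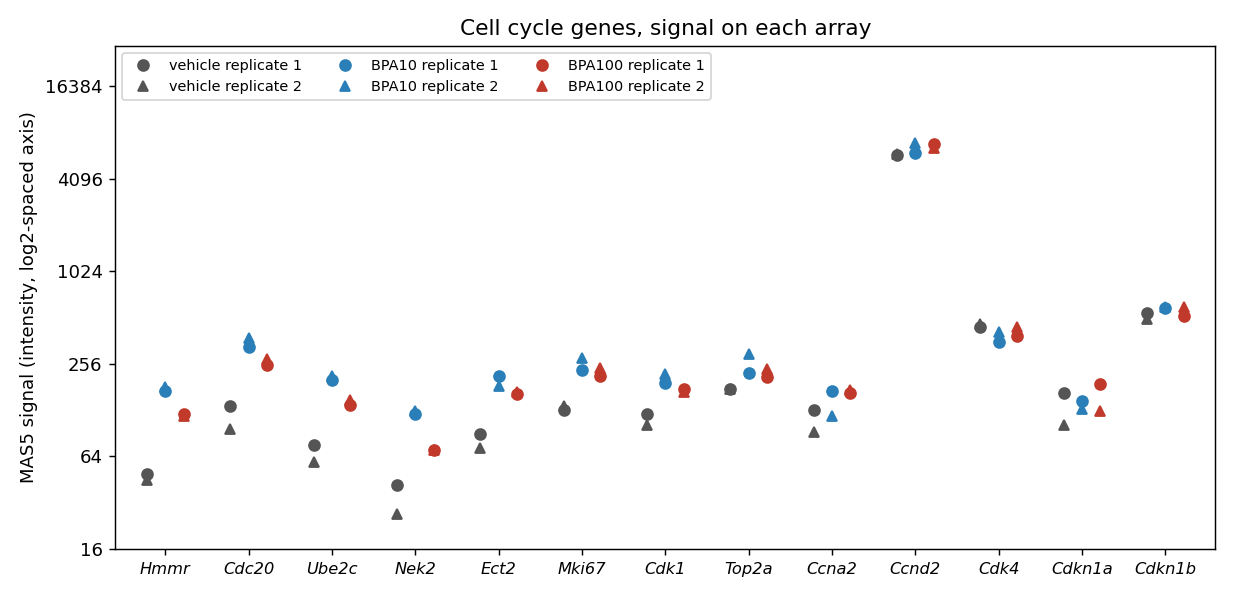
MAS5 signal (intensity, on a log2-spaced axis) of 13 cell cycle genes on each of the 6 arrays; a point is the gene's brightest probe set on 1 array, colours are the groups and marker shapes the replicates. Hmmr, Cdc20, Ube2c, Nek2, Ect2, Mki67, Cdk1 and Top2a lie higher on all 4 bisphenol-A arrays than on both vehicle arrays, while Ccna2, Cdkn1a and Cdkn1b overlap.

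Acinar-cell markers rose (camera adjusted p = 1.4e-18; adjusted p = 0.835 with an estimated correlation, which for this list was 0.826). Of 30 genes, 22 had an unadjusted p under 0.05 and 2 passed when adjusted over the list alone. The list already differed between the vehicle arrays, at 0.69 and -0.69, against 1.38 and 1.06 on the BPA10 arrays. Prss3, a trypsinogen, measured 635 and 1106 on the vehicle arrays and 3780 and 4599 on the BPA10 arrays (2.31 ± 0.36), and Rbpjl, an acinar transcription factor, 19 and 12 against 95 and 81 (2.46 ± 0.44, both adjusted p = 0.315). The brighter digestive enzyme genes Prss2, Cpa1 and Cela1 differed by 0.62, 0.83 and 0.61. Stellate-cell and fibroblast markers rose by a mean of 0.32 (24 of 29 genes higher, camera adjusted p = 7.4e-04; 0.835 with an estimated correlation; turned to lower, uncalled, with the acinar covariate, 0.892), with Thy1 at 1.25, Postn at 0.79, Acta2 at 0.61 and Col5a2 at 0.55, while Des, another member, fell by 1.17, and 2 genes passed when adjusted over the list alone. Genes disallowed in mature beta cells rose by 0.32 (19 of 20 higher, adjusted p = 0.0012; 0.835 with an estimated correlation; also turned with the acinar covariate, 0.940), with Ldha at 0.68, Oat at 0.37, Acot7 at 0.40 and Igfbp4 at 0.52, and 0 passed when adjusted over the list alone. Stellate and disallowed lists stood at 0.64 and 0.61 on BPA10 replicate 1, and at -0.00 and 0.03 on BPA10 replicate 2.

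Cholesterol and fatty acid synthesis genes rose by a mean of 0.26 (20 of 26 higher, 9 at an unadjusted p under 0.05, 2 adjusted over the list alone; camera adjusted p = 1.5e-05; 0.835 with an estimated correlation), with the sterol enzymes Nsdhl at 0.64, Idi1 at 0.59 and Fdft1 at 0.43 and the desaturase Scd1 at 0.82. Interferon response genes rose by 0.33 (20 of 28 higher, 1 adjusted over the list alone; adjusted p = 0.0014; 0.835 with an estimated correlation), with Rsad2 at 93 and 111 against 411 and 221 (1.56 ± 0.27), Mx1 at 1.49, Iigp1 at 0.88 and Gbp2 at 0.74. Genes of endoplasmic reticulum stress and folding rose by 0.22 (26 of 33 higher, adjusted p = 0.0012; 0.835 with an estimated correlation), a call lost after quantile normalization (adjusted p = 0.373). Xbp1, Derl3, Sel1l and Ero1b differed by 0.46, 0.66, 0.69 and 0.33 (Ero1b -0.00 after quantile normalization), with other probe sets of Ero1b between -0.13 and 0.03. Immediate-early and isolation-stress genes fell by 0.29 (19 of 25 lower, adjusted p = 0.0086; 0.835 with an estimated correlation), with Nr4a1 at 192 and 334 against 125 and 64 (-1.49 ± 0.35), Junb at -0.91, Socs3 at -0.65 and Ier3 at -0.35. Oxidative phosphorylation genes fell by 0.05 (35 of 59 lower, adjusted p = 0.0321; adjusted p = 0.885 with an estimated correlation), with Ndufa6, Ndufs4, Atp5g2 and Ndufb2 between -0.31 and -0.25 (other probe sets of Ndufs4 -0.11 to 0.05). Cytosolic ribosomal protein genes rose by 0.09 (32 of 40 higher, adjusted p = 0.0139; adjusted p = 0.891 with an estimated correlation) but were called lower after quantile normalization (adjusted p = 0.0013) and were not called after median centring (adjusted p = 0.0588). Rpl27a differed by 0.45, and Rps29, Rps28 and Rpl4 by 0.27, 0.27 and 0.24, which quantile normalization turned to -0.16, -0.04 and -0.08. No member of the endoplasmic reticulum, immediate-early, oxidative phosphorylation or ribosomal lists passed when adjusted over the list alone.

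Islet hormone genes were bright on all arrays. Ins2, an insulin gene, measured 3546 and 3552 on the vehicle arrays and 4873 and 4797 on the BPA10 arrays (0.45 ± 0.19, adjusted p = 0.688). Gcg, Ppy, Iapp and Sst differed by 0.38, 0.41, 0.30 and 0.25, which quantile normalization turned to -0.02, -0.01, -0.10 and -0.13, and other probe sets of Iapp gave -0.81 to 0.15. The beta-cell transcription factor Pdx1 differed by 0.37 and Nkx6-1 by 0.01, the glucose transporter gene Slc2a2 by 0.17 and the maturity marker Ucn3 by 0.03 (-0.07 and -0.01 after quantile normalization; Nkx6-1 -0.01 after median centring). The survival genes Bcl2 and Bcl2l1 differed by 0.09 (other probe sets -0.40 to 0.78) and 0.15, and the membrane estrogen receptor gene Gper1 by 0.48. Other large differences filling the places of the naming rule were Kcnk13 (1.97) and Slc12a8 (1.76), and, in the other direction, Lbp (923 and 853 against 159 and 367, -1.87 ± 0.33), Hrct1 (-1.63), Trim62 (-1.41, other probe sets 0.20 and 2.13), the imprinted noncoding RNA Kcnq1ot1 (-1.28), Wfdc1 (-1.27), the stellate-list gene Des (-1.17, other probe set -1.25) and Trpc7 (-1.13).

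In limma, 0 of 27022 probe sets passed between BPA10 and vehicle (smallest adjusted p = 0.182). An unadjusted p under 0.05 was found for 1914, of which 844 were higher and 1070 lower, where 1351 are expected by chance. That count was 874 without vehicle replicate 2 and 986 (458 and 528) with the acinar covariate, both below chance. The split was 401 higher and 1109 lower without BPA10 replicate 1, 1113 and 978 without vehicle replicate 1, 1235 and 865 with only arrays of 1 mouse, and 607 and 596 with the 60th percentile filter. The arrays of the groups did not overlap for 36.0% of probe sets, against 33.3% by chance. Camera called 10 of 33 lists, 8 higher and 2 lower; with an estimated correlation, and with fry, it was 0. The mixed test of fry, which does not ask for 1 direction, called 3: mitosis (adjusted p = 0.0224), heat shock and Schwann-cell genes (both 0.0328). Without vehicle replicate 1, 9 probe sets passed, and the endoplasmic reticulum (adjusted p = 0.263) and immediate-early lists (0.243) were lost; without vehicle replicate 2 the stellate (0.0547), disallowed (0.125), interferon (0.125), oxidative phosphorylation (0.918) and ribosomal (0.207) lists were lost. Without BPA10 replicate 1 the stellate (0.979), disallowed (0.979), oxidative phosphorylation (0.808) and ribosomal (0.984) lists were lost, and without BPA10 replicate 2 the immediate-early list turned to higher, uncalled (0.880), as this list stood at 0.05 on BPA10 replicate 1 and -0.63 on replicate 2. With only arrays of 1 mouse it turned as well (0.298; 1.5e-08 to 0.880 over its alternatives). Other settings also ended calls: the mean of a gene's probe sets for the immediate-early (0.0695) and ribosomal lists (0.177), no intensity trend for the ribosomal (0.0863) and oxidative phosphorylation lists (0.0839), and the 60th percentile filter for the latter (0.0524). Only arrays of 1 mouse ended the endoplasmic reticulum call (0.671), and the acinar covariate those of the endoplasmic reticulum (0.266) and oxidative phosphorylation lists (0.576). With that covariate the ribosomal (0.815) and acinar lists (0.471) turned to lower, uncalled.

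Mitosis and cytokinesis genes were also higher in islets of BPA100 offspring than in vehicle offspring. Their mean change was 0.63 on the log2 scale, or 1.54-fold, with 46 of 49 genes higher. Acinar-cell markers were higher by 0.44, while markers of stellate cells and fibroblasts, macrophages and duct cells were lower, by means of -0.38, -0.38 and -0.20. Immediate-early genes, which respond within minutes to stimulation or tissue handling, were lower by a mean of -0.55. The mean of the S phase genes differed by 0.01 and that of beta-cell identity genes by 0.01.

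The mitosis list rose (camera adjusted p = 1.6e-27; adjusted p = 0.644 with an estimated correlation), standing at 0.59 and 0.66 on the BPA100 arrays relative to the vehicle mean. Of its genes, 26 had an unadjusted p under 0.05, 0 passed over all probe sets and 24 passed when adjusted over the list alone. Hmmr measured 121 and 118 on the BPA100 arrays (1.33 ± 0.19 above vehicle, adjusted p = 0.367), Cdc20 250 and 276 (1.19 ± 0.20, adjusted p = 0.478), Ube2c 138 and 148 (1.08 ± 0.20) and Ect2, which starts the division furrow, 162 and 167 against 90 and 73 (1.01 ± 0.19). Mki67 differed by 0.78, Cdk1 by 0.62, Ccna2 by 0.63 and Top2a by 0.34, against 0.19 for Ccnd2, -0.14 for Cdk4, 0.25 for Cdkn1a and 0.10 for Cdkn1b, whose other probe sets gave -0.04 and -0.25. Acinar markers rose as a list (27 of 30 higher, 0 adjusted over the list alone, camera adjusted p = 2.0e-05; adjusted p = 0.862 with an estimated correlation) but stood at 0.99 on BPA100 replicate 1 and -0.11 on replicate 2. Prss3, Prss2, Cpb1 and Cela3b differed by 1.46, 0.42, 0.30 and 0.25, and Cpa1 and Cela1 by 0.43 and 0.30.

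At camera's preset correlation 5 lists of other cell types and stress responses were called lower, each with an adjusted p = 0.862 with an estimated correlation. Stellate-cell and fibroblast markers fell (25 of 29 lower, camera adjusted p = 1.3e-05), with Des at 75 and 59 against 21 and 19 (-1.69 ± 0.34; its other probe set gave 0.03), Tagln at -1.06, Col1a1 at -0.99 and Mgp at -0.80. Macrophage and myeloid markers fell (20 of 27 lower, adjusted p = 0.0012), but vehicle replicate 1 carried much of the signal: the lysozyme gene Lyz2 measured 803 and 142 on the vehicle arrays and 123 and 79 on the BPA100 arrays (-1.77), Lyz1 differed by -1.91, Cd14 by -0.79 and Fcer1g by -0.63. Duct-cell markers fell (12 of 13 lower, adjusted p = 0.0038), with the keratin genes Krt7, Krt18, Krt8 and Krt19 at -0.44, -0.33, -0.26 and -1.11. Immediate-early genes fell (22 of 25 lower, adjusted p = 1.3e-05): Fos measured 2349 and 841 on the vehicle arrays and 165 and 168 on the BPA100 arrays (-3.07 ± 0.95), Egr1 differed by -1.90, Junb by -1.59 and Nr4a1 by -1.41. Heat shock and folding genes fell by 0.22 (13 of 19 lower, adjusted p = 0.0161), led by the inducible chaperone genes Hspa1b, at 535 and 595 against 157 and 155 (-1.85 ± 0.22, adjusted p = 0.200), and Hspa1a (-1.63), with Dnajb1 at -0.69 and Dnaja1 at -0.24. When adjusted over the list alone, 1 stellate, 2 immediate-early, 3 heat shock and 0 macrophage or duct genes passed.

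Each of 4 further lists was called at the preset correlation and had an adjusted p = 0.862 with an estimated correlation. Oxidative phosphorylation genes fell by 0.08 (44 of 59 lower, adjusted p = 6.1e-04), with Atp5o at -0.52 and Atp5e, Ndufa6 and Uqcrh between -0.27 and -0.25. Disallowed genes fell by 0.19 (17 of 20 lower, adjusted p = 0.0454), a call kept in 13 of 20 alternatives besides the estimated correlation and fry. It ended with the mean of a gene's probe sets (0.0536), no filter (0.0516), the 60th percentile filter (0.0583), no intensity trend (0.0758), only arrays of 1 mouse (0.644) and without vehicle replicate 1 (0.787) or BPA100 replicate 2 (0.870). The disallowed genes with the smallest p were Igf1, Cat, Cd302 and Mgst1, at -0.87, -0.42, -0.55 and -0.49. Cholesterol and fatty acid synthesis genes rose by 0.18 (23 of 26 higher, adjusted p = 4.2e-04), with Cyp51, Insig1, Idi1 and Scd2 at 0.65, 0.46, 0.35 and 0.38. Other probe sets of Cyp51 gave -0.24 and 0.35. Genes of endoplasmic reticulum stress and folding rose by 0.08 (26 of 33 higher, adjusted p = 0.0262), a call kept in 12 of 20 alternatives and lost after quantile normalization (adjusted p = 0.524), with Ern1, Hsp90b1, Ero1a and Hspa5 between 0.24 and 0.29. These 4 lists had 0 members passing when adjusted over the list alone. Ins2 measured 4139 and 2680 on the BPA100 arrays (-0.09 ± 0.19), and Iapp, Gcg, Sst and Ppy differed by 0.20, 0.17, 0.25 and 0.16, all but Sst turning to between -0.08 and -0.01 after quantile normalization. Pdx1, Nkx6-1, Slc2a2 and Ucn3 differed by -0.07, 0.08, 0.12 and 0.47, Bcl2 and Bcl2l1 by 0.33 and -0.31, and Gper1 by 0.28. Probe sets of opposite sign were found for Iapp (-0.04), Pdx1 (0.14), Bcl2 (-0.22), Ern1 (-0.12), Hspa5 (-0.03) and Cat (0.01). The places of the naming rule were filled by Gdpd3, a phospholipase-family gene (42 and 32 against 456 and 437, 3.57 ± 0.76, adjusted p = 0.908), Ddit4l, an inhibitor of mTOR signalling (81 and 70 against 454 and 296, 2.27 ± 0.26, adjusted p = 0.200), Kcnk13 (2.01), the interferon-induced Mx1 (1.73), Siglec1 (1.52), Cdr2l (1.45, other probe set -0.16) and Rab3c, a vesicle GTPase (1.44). In the other direction stood Saa3 (705 and 26 against 5 and 9, -4.16 ± 1.21), the class II histocompatibility gene H2-Ea (343 and 419 against 52 and 36, -3.10 ± 0.49), Samd1 (-2.10), Apof (-2.05) and Tmem45a (-1.68).

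In limma, 0 probe sets passed between BPA100 and vehicle (smallest adjusted p = 0.200), and 1075 had an unadjusted p under 0.05, 570 higher and 505 lower, below the 1351 expected by chance; the split turned without BPA100 replicate 1 (450 and 554) and without BPA100 replicate 2 (550 and 789), and with the acinar covariate it was 623 and 624. The arrays did not overlap for 31.9% of probe sets. Camera called 11 lists, 4 higher and 7 lower, and 0 with an estimated correlation or with fry. The mixed test of fry called 3: mitosis and heat shock (both adjusted p = 0.0166) and interferon genes (2.8e-05). Without BPA100 replicate 1 the acinar (adjusted p = 0.730) and endoplasmic reticulum (0.0843) lists turned to lower, uncalled, and the macrophage (0.124) and cholesterol (0.0843) lists were lost. Without BPA100 replicate 2, with 6 lists called, the heat shock list turned to higher, uncalled (0.934), and the duct (0.322), stellate (0.139), oxidative phosphorylation (0.322) and disallowed (0.870) lists were lost. Without vehicle replicate 1, 5 probe sets passed and the macrophage (0.927), endoplasmic reticulum (0.645), cholesterol (0.157) and disallowed (0.787) lists were lost; without vehicle replicate 2 the acinar list turned to lower, uncalled (0.344), and the duct (0.157), heat shock (0.187) and oxidative phosphorylation (0.459) lists were lost. The heat shock call also ended on ranks (0.196) and with no intensity trend (0.0521). The endoplasmic reticulum call ended with the mean of a gene's probe sets (0.148), no filter (0.0506), no intensity trend (0.0905), only arrays of 1 mouse (0.698) and the acinar covariate (0.266). Only arrays of 1 mouse also ended the macrophage (0.776) and cholesterol calls (0.191), and the acinar covariate that of the acinar list (0.481).

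**Figure D2:**
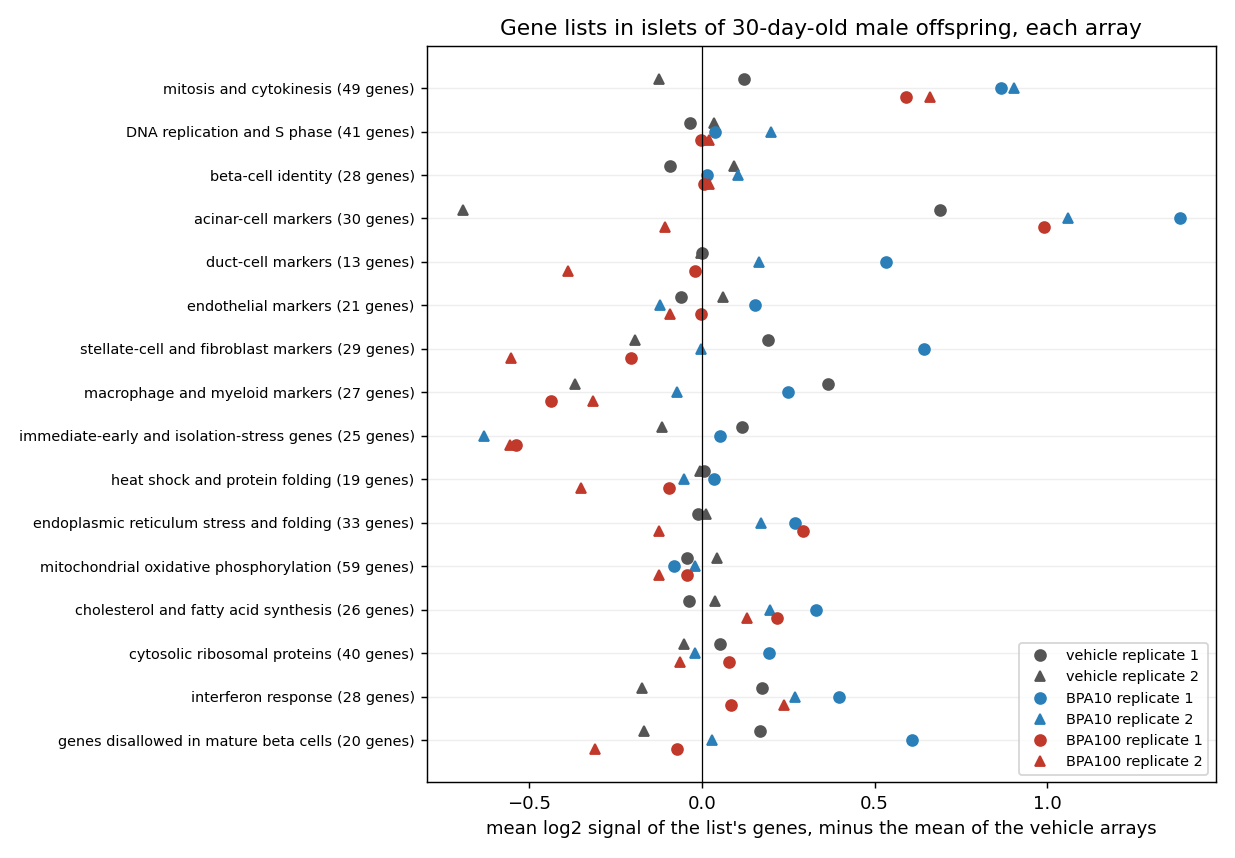
Mean log2 signal of the genes of 16 lists on each array, minus the mean of the vehicle arrays; each point is 1 array, colours are the groups and marker shapes the replicates. The mitosis list stands between 0.59 and 0.90 on the 4 bisphenol-A arrays. The acinar list differs as much between the vehicle arrays (0.69 and -0.69) as between groups. Values are shown at the deposited scaling only. After quantile normalization the ribosomal list was called lower in BPA10, and the endoplasmic reticulum list lost its calls at BPA10 and BPA100.

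Between the doses, markers of non-endocrine cells were lower in BPA100 than in BPA10 islets. Acinar markers differed by a mean of -0.78 (30 of 30 lower), stellate-cell and fibroblast markers by -0.70 (27 of 29), duct markers by -0.55 (13 of 13) and macrophage markers by -0.46 (26 of 27). Disallowed genes differed by -0.51 (20 of 20) and mitosis genes by -0.26 (40 of 49). Endothelial markers differed by -0.06. Genes of a list are not independent, so these counts overstate the evidence. The estimated correlation between genes was 0.826 for acinar, 0.658 for disallowed, 0.464 for macrophage and 0.440 for stellate lists. It was 0.164 for mitosis and 0.105 for duct genes. Acinar markers stood at 1.38 and 1.06 on the BPA10 arrays and at 0.99 and -0.11 on the BPA100 arrays, relative to the vehicle mean.

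All of these lists but the endothelial one fell from BPA10 to BPA100 by camera, with adjusted p = 9.1e-09 for acinar, 2.3e-15 for stellate, 1.1e-05 for duct, 4.6e-06 for macrophage, 1.1e-08 for disallowed and 4.6e-06 for mitosis genes. These lists, and the heat shock and ribosomal lists, each had an adjusted p = 0.910 with an estimated correlation. Heat shock genes (-0.21, 13 of 19 lower, adjusted p = 0.0418) and ribosomal protein genes (-0.08, 33 of 40 lower, adjusted p = 0.0192) fell too, the ribosomal call being lost after median centring (0.142) and turning to higher, uncalled (0.786), after quantile normalization. When adjusted over the list alone, 10 stellate and 3 heat shock genes passed, all lower, and 0 of the other 6 lists. The macrophage and duct lists stood at 0.25 and 0.53 on BPA10 replicate 1 but at -0.07 and 0.17 on replicate 2. Single genes of the naming rule were Gdpd3 (3.06 ± 0.76), Hrct1 (2.03 ± 0.34) and Lbp (1.72 ± 0.33), higher at BPA100, and Tmem45a (-2.51 ± 0.47), H2-Ea (-2.19 ± 0.49) and Samd1 (-2.10 ± 0.43), lower. Ins2 differed by -0.54 ± 0.19 and Pdx1 by -0.44 ± 0.13 (both adjusted p = 0.964). Iapp, Gcg, Sst and Ppy lay between -0.25 and -0.00, and Nkx6-1, Slc2a2 and Ucn3 at 0.06, -0.05 and 0.44, with Iapp, Sst and Slc2a2 turning to 0.09, 0.19 and 0.08 after quantile normalization. Mki67, Cdk1, Top2a, Ccna2, Ccnd2 and Cdk4 differed by -0.18, -0.26, -0.21, 0.26, 0.04 and 0.12, Cdkn1a and Cdkn1b by 0.16 and -0.08, Bcl2 and Bcl2l1 by 0.24 and -0.46, and Gper1 by -0.20. Prss2 (0.03 after quantile normalization), Cpa1 and Cela1 differed by -0.20, -0.40 and -0.30. Probe sets of opposite sign were found for Iapp (up to 0.77), Ccna2 (-0.20), Cdk4 (-0.23) and Bcl2 (-0.28).

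In limma, 0 probe sets passed between the doses (smallest adjusted p = 0.897), and 1283 had an unadjusted p under 0.05, 659 higher and 624 lower. Without BPA10 replicate 2 the count was 2019 (951 and 1068), and the split was 826 and 277 without BPA10 replicate 1 and 318 and 561 without BPA100 replicate 2. It also turned without vehicle replicate 1 (568 and 596), vehicle replicate 2 (549 and 605) or BPA100 replicate 1 (845 and 1008), and with only the groups compared (543 and 606), only arrays of 1 mouse (678 and 804), the replicate block (922 and 1082) and the 60th percentile filter (391 and 416). The arrays did not overlap for 30.7%. Camera called 8 lists, all lower in BPA100, and 0 with an estimated correlation, with fry or with its mixed test. Without BPA100 replicate 2 the heat shock list turned to higher, uncalled (adjusted p = 0.952), and the acinar (0.671) and ribosomal (0.757) lists were lost. The ribosomal list turned to higher, uncalled, without BPA10 replicate 1 (0.875) and was lost without vehicle replicate 2 (0.0504), and the heat shock list was lost without BPA10 replicate 2 (0.137), vehicle replicate 1 (0.0561) or vehicle replicate 2 (0.0582). Besides the estimated correlation and fry, the heat shock call was kept in 9 of 20 alternatives and the ribosomal call in 10. The heat shock call also ended on ranks (0.214), after quantile normalization (0.0655), with no filter (0.0550), no intensity trend (0.148), only the groups compared (0.0597), only arrays of 1 mouse (0.262) and the acinar covariate (0.125). The ribosomal call also ended with the mean of a gene's probe sets (0.152), no filter (0.0665), no intensity trend (0.162), only the groups compared (0.05001) and the acinar covariate (0.877), which turned the acinar list to higher (0.0440). Without BPA10 replicate 2, 1 probe set passed, that of Gdpd3 (4.56, adjusted p = 0.0250).

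Over both doses together, mitosis and cytokinesis genes were higher than in vehicle islets by a mean of 0.75, or 1.69-fold, with 47 of 49 genes higher. Acinar-cell markers were higher by 0.83 and immediate-early genes lower by a mean of -0.42. For acinar markers the groups overlapped: BPA100 replicate 2 stood at -0.11, between the vehicle arrays at 0.69 and -0.69, relative to the vehicle mean. Smaller differences were seen in cholesterol and fatty acid synthesis (0.22), interferon response (0.25), endoplasmic reticulum stress (0.15) and oxidative phosphorylation genes (-0.07). The mean of the S phase genes differed by 0.06, and that of beta-cell identity genes by 0.04.

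These 7 lists passed in camera. Mitosis genes rose (adjusted p = 1.9e-37; adjusted p = 0.420 with an estimated correlation, p = 0.0127 before adjustment over the lists), and the list was higher in 4 of 4 bisphenol-A arrays than in both vehicle arrays. At an unadjusted p under 0.05 stood 34 genes, and 33 passed when adjusted over the list alone. Acinar markers rose (29 of 30 higher, 2 adjusted over the list alone, adjusted p = 2.2e-14), cholesterol genes rose (21 of 26, 5.2e-06), interferon genes rose (19 of 28, 1 adjusted over the list alone, 0.0059) and immediate-early genes fell (21 of 25, 2 adjusted over the list alone, 6.4e-05), each with an adjusted p = 0.867 with an estimated correlation. Endoplasmic reticulum genes rose (28 of 33, 0.0015), a call lost after quantile normalization (0.409), and oxidative phosphorylation genes fell (43 of 59, 0.0016), each with an adjusted p = 0.966 with an estimated correlation. Hmmr differed by 1.61 ± 0.17 (adjusted p = 0.206), Cdc20 by 1.40 ± 0.17, Ube2c by 1.35 ± 0.17, Ect2 by 1.15 ± 0.17, Nek2 by 1.44 ± 0.23 and Mki67 by 0.86 ± 0.15 (adjusted p = 0.381), and each was higher in 4 of 4 bisphenol-A arrays than in both vehicle arrays. Cdk1, Top2a, Ccna2, Ccnd2 and Cdk4 differed by 0.75, 0.45, 0.50, 0.17 (Ccnd2, -0.01 after quantile normalization) and -0.20, and Cdkn1a and Cdkn1b by 0.17 and 0.14.

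Further named genes of this comparison were Kcnk13, a potassium channel gene (23 and 9 on the vehicle arrays and 56 to 67 on the others, 1.99 ± 0.37), Prss3 (1.89), Mx1 (1.61), Ddit4l (1.47) and Lrr1 (1.41). Lower values were found for the synaptic gene Nrxn3 (-1.52), Nr4a1 (-1.45), Des (-1.43), Hspa1b (-1.40), Junb (-1.25), Fam151a (-1.11), Kcnq1ot1 (-1.0) and Spata31d1d (-0.97). In the lists, Rbpjl, Prss2 and Cpa1 differed by 1.59, 0.52 and 0.63, Fos and Socs3 by -2.11 and -0.57, Xbp1, Derl3, Hsp90b1 and Ero1b by 0.33, 0.44, 0.25 and 0.28, and Ndufa6, Ndufs4, Atp5g2 and Atp5o by -0.29, -0.29, -0.26 and -0.31. Idi1, Nsdhl, Insig1 and Scd2 differed by 0.47, 0.45, 0.41 and 0.44, and Rsad2, Iigp1 and Gbp2 by 1.35, 0.72 and 0.57. Ins2, Iapp, Gcg, Sst and Ppy differed by 0.18 to 0.28, turning to between -0.06 and -0.04 after quantile normalization for Iapp, Gcg, Sst and Ppy. Pdx1, Nkx6-1, Slc2a2 and Ucn3 differed by 0.05 to 0.25 (Slc2a2 -0.03 after quantile normalization), Bcl2, Bcl2l1 and Gper1 by 0.21, -0.08 and 0.38, and Cela1 by 0.46. Probe sets of opposite sign were found for Nek2 (-0.23), Cdkn1a (-0.54), Cdkn1b (-0.18), Ccnd2 (-0.02), Iapp (-0.43), Bcl2 (-0.31), Bcl2l1 (0.01), Ero1b (-0.03) and Ndufs4 (0.12). None of these genes passed.

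In limma, 0 probe sets passed for the mean of both doses (smallest adjusted p = 0.206), and 1537 had an unadjusted p under 0.05, 729 higher and 808 lower. Without vehicle replicate 2 the count was 784, with 461 higher and 323 lower, and without vehicle replicate 1 the split was 1000 and 728. More were higher than lower also with only arrays of 1 mouse (999 and 629), the replicate block (1129 and 1092), the 60th percentile filter (536 and 492) and the acinar covariate (577 and 547). The 4 and 2 arrays did not overlap for 14.5%, against 13.3% by chance. The F test over the 3 groups called 0 (smallest adjusted p = 0.342), with 1412 at an unadjusted p under 0.05, or 876 without vehicle replicate 2. Camera called 7 of 33 lists, and 0 with an estimated correlation or with fry. The mixed test of fry called 3: mitosis and heat shock (both adjusted p = 0.0125) and interferon genes (0.0482). With only arrays of 1 mouse the immediate-early list was lost (0.316; 7.2e-10 to 0.316 over its alternatives), and BPA10 replicate 1 stood at 0.05 for it, between the vehicle arrays at 0.12 and -0.12. Without vehicle replicate 1, 7 probe sets passed in the comparison with vehicle and 5 in the F test, and the endoplasmic reticulum list was lost (adjusted p = 0.376); without vehicle replicate 2 the acinar (0.0686), interferon (0.480) and oxidative phosphorylation (0.590) lists were lost. Without BPA100 replicate 1 the endoplasmic reticulum list was lost (0.267), without BPA100 replicate 2 the interferon (0.182) and oxidative phosphorylation (0.139) lists, and without BPA10 replicate 1 the oxidative phosphorylation list (0.0769). The acinar covariate ended the endoplasmic reticulum (0.168) and oxidative phosphorylation calls (0.109) and turned the acinar list to lower, uncalled (0.902). Only arrays of 1 mouse ended the endoplasmic reticulum call (0.550), and ranks the interferon call (0.0587).

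**Figure D3:**
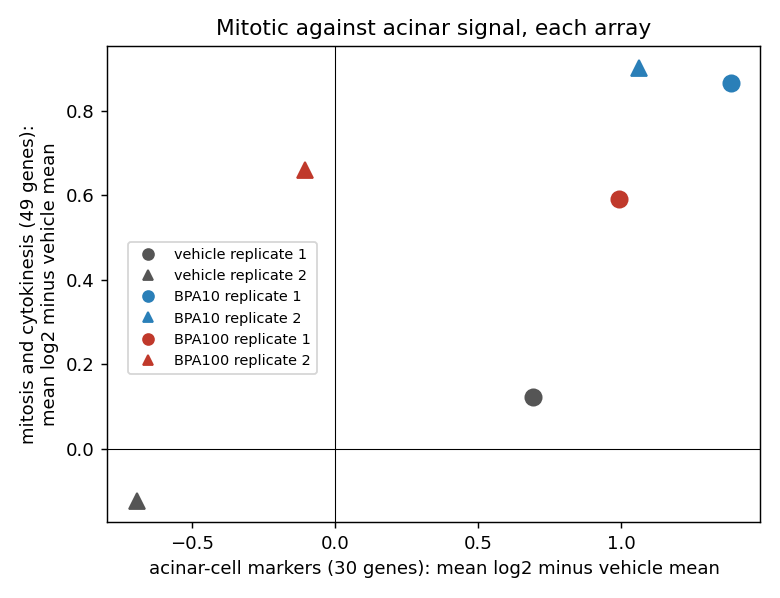
Mean log2 signal of the 49 mitosis and cytokinesis genes (vertical axis) against that of the 30 acinar-cell markers (horizontal axis), both minus the mean of the vehicle arrays; each point is 1 array, colours are the groups and marker shapes the replicates. BPA100 replicate 2 lies at -0.11 for acinar markers and 0.66 for mitosis genes, and vehicle replicate 1 at 0.69 and 0.12.

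The log2 changes of the doses against the same vehicle arrays correlated across probe sets, which are not independent replicates, with r = 0.520. Unchanged groups simulated against shared controls gave a mean of 0.50 (0.480 to 0.517 over 200 simulations). The covariance was 0.0654, against 0.0444 simulated, a difference of 0.0210. The simulated noise was drawn from limma's moderated spread. Between replicate arrays the log2 difference had a standard deviation of 0.476 to 0.490. The excess of 0.0210 rests on that choice of spread, so it is no measure of shared change. Without vehicle replicate 1 the correlation was 0.736, where unchanged groups of the same sizes gave 0.667, and without BPA100 replicate 1 it was 0.278, where they gave 0.408. Without vehicle replicate 2 it was 0.567, also below its simulated 0.666, so the sign of the excess depended on the array left out. At an unadjusted p under 0.05, 209 probe sets were higher at both doses and 153 lower at both. Unchanged groups with shared controls, simulated after these counts were seen, gave a mean of 147 higher at both (117 to 179 over 200 simulations). They gave 148 lower at both (112 to 178), so the number of lower ones lay within that range. The simulated probe sets were independent. On average 1299 had such a p at BPA10 and 1302 at BPA100, against 1914 and 1075 observed. The simulation therefore cannot say whether 209 exceeds what unchanged, correlated genes would give. The doses were not compared each with its own vehicle array, so the shared controls were not removed.

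Several lists passed in no comparison by camera at its preset correlation. G1 cyclins and cyclin-dependent kinases had means of 0.13 at BPA10 and 0.04 at BPA100, cell cycle inhibitors 0.04 and 0.05, pro-apoptotic genes 0.04 and -0.03, and anti-apoptotic genes 0.02 and -0.01. Alpha-cell markers stood at -0.01 and 0.04, markers of delta and PP cells at 0.01 and 0.01, endothelial markers at 0.02 and -0.05, lymphocyte markers at 0.28 and -0.03, and Schwann-cell and neuronal markers at 0.18 and 0.04. Genes of insulin granule exocytosis differed by -0.12 and -0.05, of glycolysis by 0.02 and -0.06, of the citric acid cycle by -0.01 and 0.01, and of fatty acid oxidation by 0.08 and 0.01. Insulin and growth factor signalling genes had means of 0.04 and -0.05, genes of beta-cell growth in pregnancy 0.13 and 0.07, estrogen receptors and target genes 0.18 and 0.14, xenobiotic and antioxidant genes 0.09 and -0.08, and chromatin regulators 0.03 and -0.01. The smallest camera adjusted p among these lists was 0.0616, for the Schwann-cell list at BPA10, which the mixed test of fry called (adjusted p = 0.0328). In 18 of 132 list results the mean, the median and the test differed in sign, and 0 of these were called; they included alpha-cell, endothelial and heat shock genes at BPA10, and G1 cyclin, anti-apoptotic, lymphocyte, citric acid cycle and fatty acid oxidation genes at BPA100. Red blood cell markers (2 genes) and sex-linked genes (4 genes) were too few for the test. Relative to the vehicle mean, the red blood cell genes stood at 1.33 and 0.22 on the BPA10 arrays and at 0.29 and -0.53 on the BPA100 arrays, and the sex-linked genes between -0.32 and 0.05 on the 4 arrays.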

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

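The tests of explanations reported here were chosen after the result was seen. The exception is the test of the mitosis list against array scaling, which was written down before its result. The camera, fry and limma results between the doses were planned.

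Between the doses, camera at its preset correlation called 8 lists. With an estimated correlation each had an adjusted p = 0.910, with fry the smallest was 0.771, and limma called 0 probe sets, with 1283 at an unadjusted p under 0.05, so a difference by dose rests on that preset. The log2 change, BPA100 minus BPA10, was -0.26 for mitosis and cytokinesis, -0.78 for acinar, -0.55 for duct, -0.70 for stellate-cell and fibroblast and -0.46 for macrophage markers. It was -0.21 for heat shock genes, -0.080 for cytosolic ribosomal proteins, which turned to higher, without a call, after quantile normalization, and -0.51 for genes disallowed in mature beta cells. Outside the gene tests, the control probe sets for 18S ribosomal RNA were higher on all 4 bisphenol-A arrays, by a mean of 0.757 on the log2 scale. The mean of those for beta-actin was higher by 0.149, which fell to 0.039 after quantile normalization. The hybridization spike controls differed by 0.232 (0.364 at BPA10 and 0.101 at BPA100), the poly-A spike controls by 0.134 and Gapdh by -0.155. For these, not all 4 bisphenol-A arrays lay above both vehicle arrays.

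Mitotic genes were higher on all 4 bisphenol-A arrays, by 0.755 ± 0.0909 (SE), while the highest of 10000 random lists matched on size and brightness shifted by 0.181, which argues against array scaling as the whole cause. Acinar cells as the whole cause are argued against by the fit with the acinar list as a covariate, in which the change stayed at 0.689 ± 0.117 (95% interval 0.188 to 1.19, 2 degrees of freedom); vehicle replicate 1 stood at 0.69 for acinar markers and 0.12 for mitosis, and BPA100 replicate 2 at -0.11 and 0.66. Chance differences between arrays, which carried RNA of 1 to 5 mice, stay open. The real split was the 1 of 15 splits of the 6 arrays into 4 and 2 that gave a difference as large. It gave 0.755 against 0.572 for the highest other, and 15 splits are too few for a share under 0.05. Litter and isolation day are not in the labels, so differences that go with them could not be tested and stay open. RNA quality stays open too: the 18S controls rose on the same 4 arrays, and with them as a covariate the change was 0.777 ± 0.230 (95% interval -0.21 to 1.77), resting on BPA10, which held 95.4% of the spread of 18S within groups. An effect of the exposure was not tested apart from these and may also account for the pattern.

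The rise of the 18S controls, at 9.90 to 10.57 on the bisphenol-A arrays against 9.32 and 9.46 on the vehicle arrays, was set against the 500 probe sets nearest in brightness. Their median change was -0.016, and 0.6% of them changed by as much, which argues against array scaling; quantile normalization and median centring left the rise at 0.758 and 0.751. Degraded RNA stays open: the 3' to 5' log2 ratio of the beta-actin and Gapdh controls differed by 0.082 ± 0.066 (SE), with a 95% interval of -0.13 to 0.29. The 3' to 5' log2 ratio of 18S itself was 0.73 on BPA10 replicate 2, the array with the highest 18S, and -0.79 to -0.18 on the other 5. How much ribosomal RNA was carried through the amplification, and any effect of the exposure itself, were not tested.

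The means of stellate markers and disallowed genes were lower at BPA100 than at BPA10. Relative to the vehicle mean, the stellate list stood at 0.64 and -0.00 on the BPA10 arrays and at -0.20 and -0.55 on the BPA100 arrays. The disallowed list stood at 0.61 and 0.03 at BPA10 and at -0.07 and -0.31 at BPA100. Chance differences between single arrays were not tested for these lists and stay open. A larger share of all non-endocrine cells at BPA10 stays open: acinar (-0.78), duct (-0.55) and macrophage markers (-0.46) were lower too, and endothelial markers, at -0.06, differed from stellate ones by 0.634 ± 0.278 (SE between arrays), with a 95% interval of -0.25 to 1.52. That stellate cells carried the disallowed transcripts also stays open. With the stellate list as a covariate the change of the disallowed list went from -0.51 ± 0.29 (95% interval -1.43 to 0.41) to 0.088 ± 0.052 (-0.14 to 0.31), so the interval held 0 before and after, and the lists share 1 gene. An effect of dose was not tested apart from these and stays open.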

How the results depend on the processing

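The acinar list as a covariate was the only alternative chosen after the data were seen. With an estimated correlation, and with fry, 0 lists were called in each of the 4 comparisons, so every list call with a direction rests on the preset correlation. The mitosis list had the smallest fry adjusted p at BPA10 (0.0770) and BPA100 (0.223), and neither passed. Between the doses its fry adjusted p was 0.771. The mixed test of fry, which asks for change in either direction, called 3 lists at BPA10, 3 at BPA100, 3 for the mean and 0 between doses, with mitosis at 0.0224, 0.0166 and 0.0125. Apart from these tests, mitosis genes kept their call in 20 of 20 alternatives in each 2-group comparison. For the mean of both doses it was 19 of 19. With camera on ranks, their adjusted p was 1.6e-13 at BPA100 and 3.5e-15 for the mean. Cholesterol genes at BPA10 and for the mean also kept their call in all of these alternatives. So did immediate-early genes at BPA100, and stellate, duct, macrophage (0.0282 with the acinar covariate) and disallowed genes between doses. All of these alternatives kept the preset correlation, so they cannot show that a call holds without it. Of 713 values of called lists under these alternatives, 614 kept the call, 83 lost it and 16 turned; of 2082 values of uncalled lists, 64 were called. Only the groups compared could not be run for the mean of both doses, the F test or the shared change. The cause of these losses was not tested unless named.

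Counts of probe sets past the threshold were 0 in each comparison with the settings used throughout. With only the groups compared they were 1 at BPA10 and 4 at BPA100, and with the acinar covariate 2 at BPA100 and 1 in the F test. Leaving out an array in turn gave 0 to 9 at BPA10, 0 to 5 at BPA100, 0 to 1 between doses, 0 to 7 for the mean and 0 to 5 in the F test, the highest without vehicle replicate 1, or between doses without BPA10 replicate 2. Such fits have fewer degrees of freedom and assume that the lone array varies like the others. Lists called at BPA100 numbered 6 to 11, with 6 without BPA100 replicate 2. With only arrays of 1 mouse, 11 lists were called for the mean of both doses, against 7. The correlation of the dose effects ran from 0.278 without BPA100 replicate 1 to 0.736 without vehicle replicate 1, where unchanged groups of those sizes gave 0.408 and 0.667.

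With the replicate number as a block, 7 probe sets passed at BPA100, 1 for the mean of both doses, 2 in the F test and 0 elsewhere. The numbers do not pair the arrays: differences between replicates correlated across groups by 0.19, 0.20 and 0.08, over 2 numbers only.

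Some lists turned direction, with these adjusted p. Ribosomal proteins turned after quantile normalization at BPA10 (0.0013) and between doses (0.786), and with the acinar covariate at BPA10 (0.815). Immediate-early genes at BPA10 turned with only arrays of 1 mouse (0.298). With the acinar covariate, the acinar list itself turned at BPA10 (0.471), between doses (0.0440) and for the mean (0.902), as did stellate (0.892) and disallowed genes (0.940) at BPA10; for the acinar list this follows from the construction. Leaving out an array gave 1.5e-08 to 0.880 for immediate-early genes at BPA10, 1.0e-21 to 0.730 for acinar markers, 1.8e-05 to 0.934 for heat shock and 3.1e-10 to 0.645 for endoplasmic reticulum genes at BPA100. Between doses it gave 2.6e-04 to 0.952 for heat shock and 1.2e-04 to 0.875 for ribosomal proteins.

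Of 4158 values of named genes under alternatives, 3713 moved by less than 1 SE, 433 by more, 80 changed sign and 12 passed, those of Gdpd3, H2-Ea, Hspa1b and Ddit4l. Of 88 counts at an unadjusted p under 0.05, 73 stayed within 1.5 times, 8 were higher and 7 lower. Dim probe sets limit what can be seen: 40% of probe sets fell below the brightness filter.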

Other observations

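The genes of the next 2 paragraphs were chosen after their values were seen, as was the difference of mitosis and S phase genes.

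A vehicle array made from 1 mouse stood far below the other 5 for some genes, picked from those that passed without vehicle replicate 1. Reg2, Reg3a and Reg3b, genes of secreted proteins, had signals of 390, 24 and 326 on vehicle replicate 2. On vehicle replicate 1, the pool of 5 mice, they measured 7547, 1869 and 4790. Vehicle replicate 2 was also the lowest of the 6 arrays for the acinar list, at -0.69 against 0.69 on vehicle replicate 1. On the BPA10 arrays the Reg genes measured 10570 and 8025, 3674 and 1902, and 10721 and 5763. On the BPA100 arrays they measured 3341 and 2619, 222 and 95, and 1798 and 2966. They did not follow the acinar list on all arrays. BPA100 replicate 1 stood at 0.99 for that list, above vehicle replicate 1, but was lower for each of these Reg genes. The class I histocompatibility gene H2-Q2 measured 11 on vehicle replicate 2 and 826 to 1604 on the other 5 arrays, the signalling ligand Lefty1 2 against 67 to 138, and a probe set of the kinase Stk17b 8 against 73 to 182. These genes passed at BPA10 in limma when vehicle replicate 1 was left out, and with all 6 arrays their adjusted p was 0.61 or more.

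Other genes differed between single arrays. Saa3, an acute-phase gene, measured 705 on vehicle replicate 1 and 5 to 29 on the other 5 arrays, and the lysozyme gene Lyz1 2003 against 138 to 731. Fos and Egr1 measured 2349, 841 and 2165, and 988, 521 and 1222, on the vehicle arrays and BPA10 replicate 1, and 165 to 183 and 173 to 211 on the other 3. Between the groups, a probe set of Golt1b, a Golgi transport gene, measured 89 and 36 on the vehicle arrays, 274 and 247 at BPA10 and 581 and 421 at BPA100, while its brighter probe set lay between 252 and 321 on all 6 arrays.

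The mean of the mitosis list minus that of the S phase list, relative to the vehicle mean, stood at 0.83 and 0.70 on the BPA10 arrays and at 0.59 and 0.64 on the BPA100 arrays, against 0.16 and -0.16 on the vehicle arrays. It restates the list means of each array and was not tested.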
